A study of Rattus norvegicus with 6 samples.

How the data were processed

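Ovary RNA from lean and overfed rats was hybridized to 6 Affymetrix arrays, 3 per group, each holding the RNA of 1 pool. Per the labels, total RNA was extracted with TRI reagent and cleaned on RNeasy columns with DNase digestion, and biotin-labelled RNA was made with the manufacturer's kit. The submitters' processing notes name GCOS, Affymetrix's operating software, with no version. The probe set summary, any normalization between arrays, any filter and the logarithm's base are not given in the sources used here. The deposited values are on a log scale, taken here as log2, and were centred before they were deposited: the median of the 6 values was 0 within 1e-06 in each of 31099 probe sets. The level of a probe set, and so its signal over background, is therefore unknown here. Base 10 was ruled out, because the largest range of a probe set, 6.22, would then be a 1673080-fold difference and a 16-bit scanner reaches 65536. Natural logarithms were not ruled out. If the values are natural logarithms, each fold printed here is too small, whereas test results other than those with a fold threshold stay as they are. No scanner files were used here.

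Gene names came from the platform annotation supplied with the values, and symbols were updated through Entrez identifiers in a RefSeq gene table, which held 20758 of the named probe sets' identifiers. After 57 array control probe sets were left out, 31042 probe sets were tested. Of these, 20826 had 1 gene name, 436 had several and were not named, and 9780 were unnamed here. They covered 14217 genes. Where a gene had several probe sets, its representative was chosen by a RefSeq mRNA accession first, then by the probe set type (unique before shared), then by the lowest identifier. The table held 0 columns of other series.

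Overfed was compared with lean in limma 3.58.1 under R 4.3.3, with lmFit and eBayes, 2 groups, no covariate, two-sided p-values and Benjamini-Hochberg adjustment over all tested probe sets, at a threshold of 0.05. A looser count, at an unadjusted p under 0.05 and a difference of at least 1.5-fold, is given as a description. Gene lists were compared with camera on 1 representative probe set per gene, with the preset inter-gene correlation of 0.01, for 37 lists with at least 5 measured genes and adjusted over the lists. Camera with an estimated correlation and fry were run beside it. The lists held 852 different genes, of which 744 were found by current or older symbol. List means are means of log2 differences over genes, with the SE over genes, which are not independent replicates. Exact permutation tests over pools were two-sided. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

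The groups, the tests, the lists and the rule for named genes were set before the data were examined. The rule took Egr1 to Egr4, the 10 genes with the largest difference in each direction whose groups did not overlap, the 4 members with the lowest unadjusted p in each of 3 primary lists (immediate-early, cytokine and steroidogenesis genes) and in each list past camera's threshold, and 2 members of each cell type list. Genes past the adjusted threshold were to come first, and since there were 0, the largest differences at an unadjusted p under 0.01 were taken. Genes without a standard symbol were left out. Dyrk3, Pax8 and the genes of the closing section outside this rule were named after their values were seen.

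The centred values forced 4 departures from the plan. The plan had a variance trend over the mean, a filter on the 25% dimmest probe sets, the brightest probe set as a gene's representative, and the 2 brightest members of each cell type list. None has a meaning without levels. The fit without a trend, no filter, the representative rule above and the first 2 measured members of each list took their place. The fit with the trend was added as an alternative.

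The scripts were tested on simulated data for the comparison of overfed with lean, with 31042 probe sets and 50 changed at each of 4 sizes. The adjusted test called 9 of 50 at 1.5-fold, 41 at 2-fold, 48 at 4-fold and 50 at 8-fold, with 4 false calls. A list shifted by 0.5 had a camera adjusted p of 5.81e-38, 0.0105 with an estimated correlation and 0.000986 in fry, with 0 false list calls. The simulated probe sets varied independently. In the real data the genes of some lists moved together, with an estimated correlation of 0.50 in the oviduct list and 0.81 in the smooth muscle list. The simulation therefore gives no rate of false or missed list calls for these data. Its spread between pools was drawn alike for changed and unchanged probe sets, so it gives no rate of missed probe sets either. Chosen before the data were examined were these alternatives: quantile normalization, array median centring, a trend with a robust prior, array weights, the pool number as a block, leaving out each pool, both other list tests, and the mean of all probe sets of a gene. Chosen after seeing the data were the trend alone, a filter on the SD, named probe sets only, the oviduct list's mean or the Hox genes' mean as a covariate, leaving out lean pool 3 and overfed pool 1 together, and a natural-log reading.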

Results

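Gene expression was measured in the ovaries of pregnant rats on Affymetrix arrays, 6 arrays in all. Female rats had received liquid diets through a feeding tube (total enteral nutrition) for 28 days, at 155 kcal per kg of metabolic body weight in the lean group and 220 kcal in the overfed group. They were then mated with lean males, and the ovaries were taken 4.5 days after mating. Each array held 1 RNA pool, 3 lean and 3 overfed. The labels used here do not say how many animals went into a pool, so limma's p-values for single probe sets measure the spread between pools. Camera's p-values for lists do not measure that spread alone. They set a list's genes against other genes and, at the preset correlation of 0.01, treat them as nearly independent. The deposited values are log values relative to each probe set's own median over the 6 arrays, read here as log2, so that differences between pools are known but levels are not. Array medians lay between -0.0094 and 0.0099. The SD over probe sets was 0.14 to 0.29, with the largest value in overfed pool 1. Lean pool 3 stood apart in the array controls, where the mean of 9 hybridization control probe sets was 0.53 and the 3' minus 5' difference of beta-actin was 0.36, against at most 0.035 and 0.061 in the other pools. The hybridization control means did not overlap between the groups. They were 0.035, 0.029 and 0.53 in lean pools 1 to 3 and -0.026, -0.045 and -0.23 in overfed pools 1 to 3. The number of pools limits the precision.

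The comparison of overfed with lean ovaries asks which ovarian genes differ with overfeeding, and the series names inflammation and the transcription factor Egr1 as its subjects. The list of oviduct and ciliated epithelium markers was lower in the overfed pools by far more than any other gene list, with a mean log2 difference of -0.90 (SE 0.11 over 13 genes). Interferon-stimulated genes (+0.25, SE 0.052 over 27 genes), granulosa cell genes (+0.22, SE 0.061 over 19), macrophage markers (+0.13, SE 0.036 over 25) and cell cycle genes (+0.13, SE 0.059 over 32) were higher. Genes of fatty acid synthesis, adipocytes, B and plasma cells and antioxidant defence were lower. Egr1 differed by +0.21 (SE 0.20), within the spread of the pools. The 9 lists named here, 4 higher and 5 lower, were those past an adjusted p of 0.05 in limma's camera test among 37 lists. None of the 37 passed with an estimated inter-gene correlation (smallest adjusted p = 0.638) or in fry (smallest adjusted p = 0.331). Camera compares a list with the other genes, whereas fry asks whether its genes move on balance one way and compares it with no other genes. The exact two-sided permutation test over pools gave p = 0.2 for macrophage markers and p = 0.4 for adipocyte markers. For the other lists past camera's threshold the exact permutation test gave p = 0.1, the smallest possible with 3 against 3 pools. The cytokine and glycolysis lists, which camera did not call, also had an exact permutation test p = 0.1. Without lean pool 1 the camera count was 4 lists. With the oviduct list's mean per pool as a covariate, 2 of the 8 other lists kept their call, cell cycle (+0.21, adjusted p = 8.5e-09) and antioxidant defence (-0.11, adjusted p = 0.0269). Granulosa genes at +0.21 (adjusted p = 0.164) and macrophage markers at +0.12 (adjusted p = 0.135) kept their size without passing, while interferon genes (0.066), fatty acid synthesis (-0.066) and B and plasma cells (-0.092) moved toward 0 and adipocyte markers turned to 0.14. The covariate itself separates the groups, so calls kept or lost under it cannot tell the oviduct list's level from diet.

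Single probe sets did not pass. Of 31042 tested, 0 had a limma adjusted p under 0.05, and the smallest adjusted p was 0.623. At an unadjusted p under 0.05 there were 2070, 1027 higher and 1043 lower, where 1552.1 would be expected with no difference. Of these, 403 differed by at least 1.5-fold, and 355 of the 403 were lower in overfed ovaries against 48 that were higher. Without lean pool 2 this count was 650, of which 576 were lower. The higher probe sets numbered 90 without overfed pool 1, 76 without overfed pool 2 and 74 without lean pool 2, and without lean pool 3 and overfed pool 1 together the counts were 93 higher and 228 lower. The groups did not overlap in 3935 probe sets (12.7%), where chance gives 10%. With a robust prior and a trend over the mean, which has no meaning in centred values, limma called 1, the kinase gene Dyrk3 (-1.50). With the 50% of probe sets of smaller SD left out, it called 62, of which 61 were lower in overfed ovaries. That filter gave 19 false beside 153 true calls in simulated data, against 4 false and 148 true without it. In simulated data of this size, whose probe sets varied independently, 41 of 50 probe sets changed 2-fold and 9 of 50 changed 1.5-fold passed the adjusted threshold. The spread between pools was drawn there in the same way for changed and unchanged probe sets. In the real data Lbp at -2.21 (SE 0.34) and Rsph1 at -1.69 (SE 0.41) did not pass. The simulated shares therefore do not tell how many differences of these sizes were missed here.

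**Figure D1:**
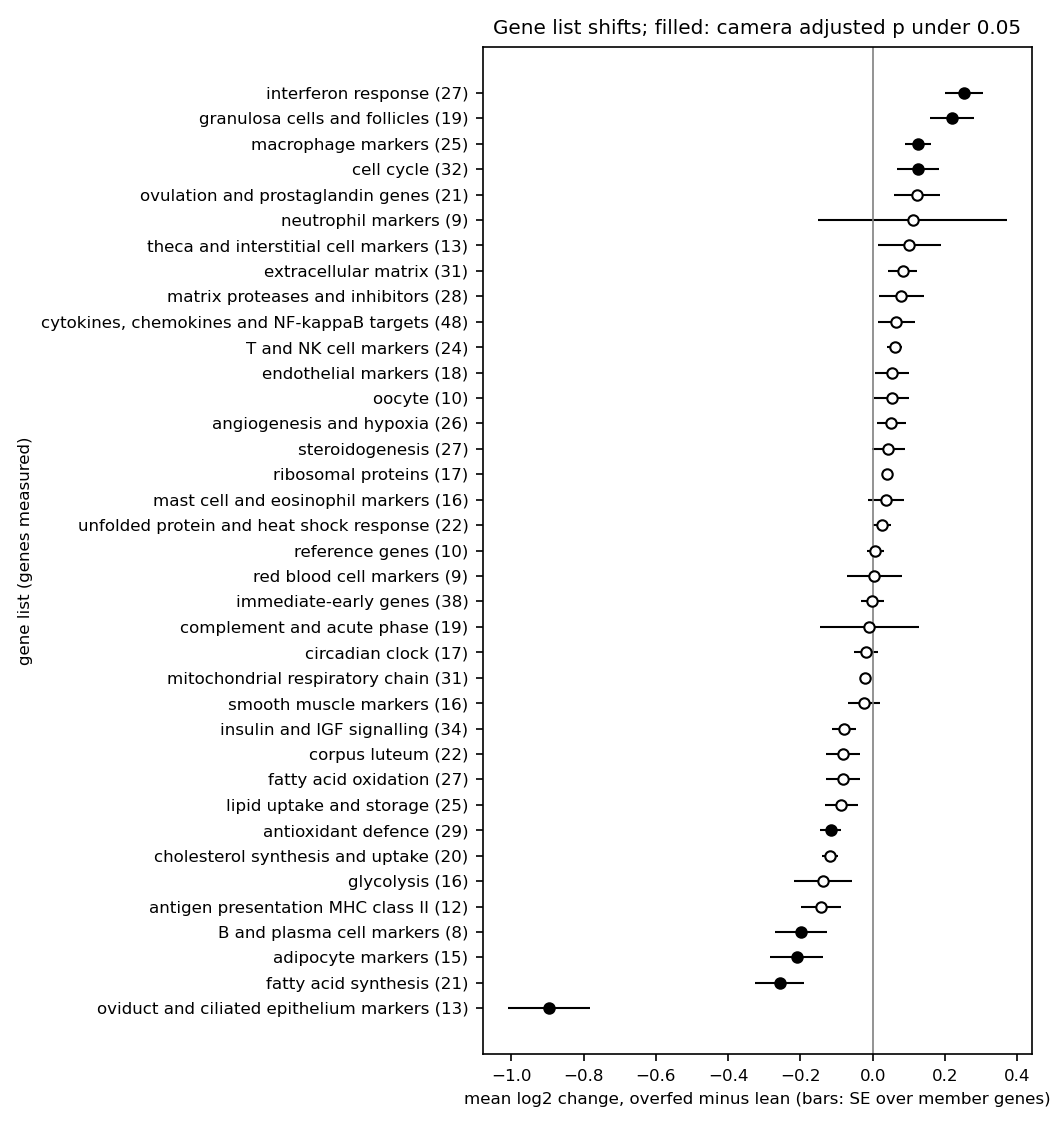
Mean log2 difference, overfed minus lean, of each of 37 gene lists, with bars for the SE over member genes and the number of measured genes in brackets. Filled points passed camera's adjusted threshold with the preset correlation, and the oviduct and ciliated epithelium list at -0.90 lies apart from the others, which lie between -0.26 and 0.25.

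Egr1, an immediate-early transcription factor induced by growth factors and gonadotropins, had relative values of 0.31, -0.20 and -0.43 in the lean pools and 0.31, -0.07 and 0.07 in the overfed pools. Its difference of +0.21, or 1.16-fold, had a limma adjusted p of 0.888, and an exact two-sided permutation test gave p = 0.4, where 3 against 3 pools cannot give less than 0.1. The difference was 0.05 without lean pool 3, 0.42 without lean pool 1 and -0.05 without lean pool 3 and overfed pool 1. Egr1 had 1 probe set. Egr2 differed by +0.59 (SE 0.21, unadjusted p = 0.0265, adjusted p = 0.708) in one probe set and by -0.01 in its other. Egr3 differed by -0.19 (adjusted p = 0.824), and the 2 probe sets of Egr4 by -0.03 and -0.13, the first of which turned to 0.0056 with quantile normalization. Over 38 immediate-early genes the mean was -0.0011 (15 higher, 23 lower, adjusted p = 0.902). Beside Egr2, the members with the lowest unadjusted p-values were the zinc finger factor Klf6 (+0.31, SE 0.093) and the MAP kinase phosphatases Dusp2 (+0.37, SE 0.13) and Dusp1 (-0.36, SE 0.17). Their limma adjusted p-values were 0.647, 0.702 and 0.787. Of the 38 genes, 3 had an unadjusted p under 0.05, and 0 passed when adjusted over the list alone.

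**Figure D2:**
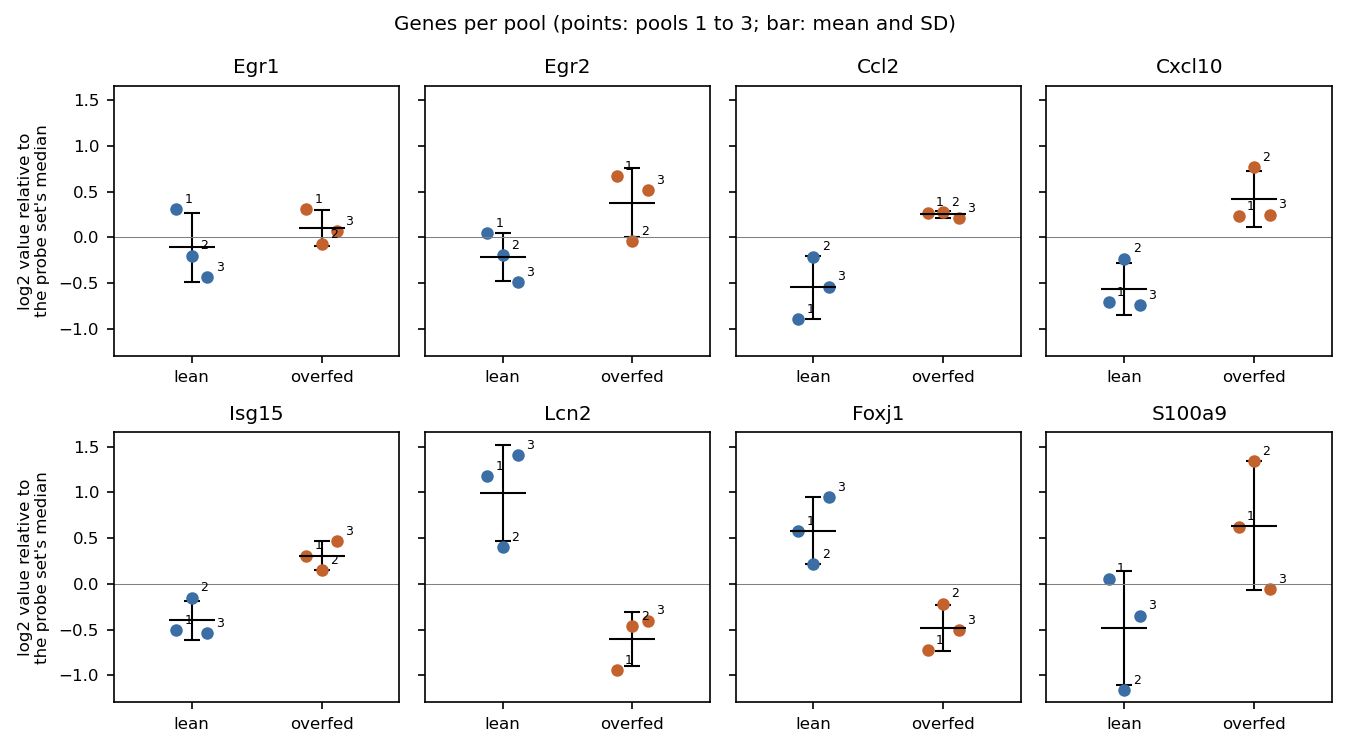
Log2 values relative to the probe set's median over the arrays, for 8 genes in the 3 lean and 3 overfed pools, with each pool as a numbered point and the group mean and SD as bars. Egr1 overlaps between the groups, while Ccl2, Cxcl10, Isg15, Lcn2 and Foxj1 do not.

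Inflammatory genes went in both directions. In the list of 48 cytokines, chemokines and NF-kappaB targets, 31 were higher and 17 lower in overfed ovaries, with a mean of +0.07 (SE 0.052, adjusted p = 0.278). Adjusted over the list alone, 3 members passed, against 0 over all probe sets. They were the monocyte chemokine Ccl2 (+0.80, SE 0.17, 1.74-fold), the interferon-induced chemokine Cxcl10 (+0.97, SE 0.19, 1.97-fold) and Lcn2, a siderophore-binding protein secreted by epithelia and neutrophils, at -1.60 (SE 0.27). The membrane-bound chemokine Cx3cl1 was at -0.34 (unadjusted p = 0.01). The neutrophil alarmins S100a8 (+1.08, SE 0.48) and S100a9 (+1.12, SE 0.41) overlapped between the groups, and without overfed pool 2 they were at 0.62 and 0.77. The 9 neutrophil genes, 7 higher and 2 lower, had a mean of +0.11 (adjusted p = 0.352), which was 0.012 without lean pool 2. The complement and acute phase genes showed 11 higher and 8 lower members. Their mean was -0.0093 and their median 0.13, camera's direction was upward (adjusted p = 0.296), and the lowest member was the lipopolysaccharide-binding protein Lbp (-2.21, SE 0.34). Over lean pools 1 to 3 Lbp (1.34, 0.61 and 1.99) and Lcn2 (1.18, 0.40 and 1.40) had the pool order of the oviduct list's means, but not over the overfed pools. Against that list's 5 ciliary genes alone, Lbp (-1.22, -0.61 and -0.86 in overfed pools 1 to 3) had the same order over all 6 pools. Those genes had means of -1.43, -0.21 and -0.80 in the overfed pools. Lcn2 (-0.94, -0.46 and -0.40) shared only their lowest value in overfed pool 1. Whether they were lower as epithelial genes was not tested.

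The interferon list shifted upward, with 22 of 27 genes higher (adjusted p = 1.7e-06, and adjusted p = 0.638 with an estimated correlation). Unadjusted, 12 members passed, all higher, and 1 passed adjusted over the list alone. The ubiquitin-like modifier Isg15 was at +0.71 (SE 0.14, 1.63-fold), the antiviral GTPase Mx1 at +0.75 (SE 0.24), Ifit3 at +0.52 (SE 0.16) and Gbp2 at +0.45 (SE 0.13). Over all alternatives Isg15 ran from 0.22 to 0.83, Mx1 from -0.040 to 0.93, Ifit3 from 0.050 to 0.625 and Gbp2 from 0.30 to 0.57. The list's shift was +0.19 to +0.29 with any 1 pool left out. With the oviduct list's mean as a covariate it was 0.066 (adjusted p = 0.495), in a fit whose covariate separates the groups itself. Macrophage markers also shifted upward, with 19 of 25 higher (adjusted p = 0.00276, and adjusted p = 0.656 with an estimated correlation), and this call was lost without lean pool 1 (+0.09, adjusted p = 0.086) or overfed pool 1 (+0.10, adjusted p = 0.0533). The mannose receptor Mrc1 (+0.40, SE 0.096), the lectin Clec10a (+0.33), C1qa (+0.25) and the leukocyte phosphatase Ptprc (+0.28) had the lowest p-values, while Cd68 (+0.03) and Adgre1 (+0.21) had adjusted p-values of 0.979 and 0.829. B and plasma cell genes shifted downward, 7 of 8 lower, with a mean of -0.20 (adjusted p = 0.0173, and adjusted p = 0.638 with an estimated correlation). They were led by the B cell antigen Ms4a1 (-0.33, SE 0.081), which passed adjusted over the list alone, and the plasma cell chaperone cofactor Mzb1 (-0.40, SE 0.14). Pou2af1 was at -0.16, Jchain at -0.47 (-0.16 without overfed pool 1) and Cd79b at +0.12 (0.052 without lean pool 2). The other probe set of Jchain was also at -0.47 (unadjusted p = 0.00522), without overlap between the groups. The call of the B and plasma cell list was lost without lean pool 1 (-0.17, adjusted p = 0.0745) or overfed pool 1 (-0.15, adjusted p = 0.14). MHC class II genes (10 of 12 lower, mean -0.14, adjusted p = 0.0854, with Cd74 at -0.22 and RT1-Da at -0.11), T and NK cell genes (18 of 24 higher, mean +0.06, adjusted p = 0.216, with Cd3d at +0.19 and Cd3e at +0.10) and mast cell and eosinophil genes (10 of 16 higher, mean +0.04, adjusted p = 0.494, with Cpa3 at +0.25 and Cma1 at +0.07) did not pass. MHC class II did pass without lean pool 1 (-0.26, adjusted p = 0.00112) but was at -0.048 without lean pool 2, and T and NK cell genes passed without lean pool 2 (+0.12, adjusted p = 0.00818) but were at -0.0073 without lean pool 1.

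Among ovarian functions, steroidogenesis showed no shift past the threshold. Of 27 genes 13 were higher and 14 lower, the mean was +0.04, the median -0.0024 and camera's direction downward (adjusted p = 0.921). The mean was 0.0016 without overfed pool 3 and 0.12 without overfed pool 1. Cyp17a1, the androgen-producing enzyme of theca cells, was at +0.69 (SE 0.27, unadjusted p = 0.0351), and it turned to -0.13 with the oviduct list's mean as a covariate. Hsd17b1, which activates estrogen in granulosa cells, was at +0.37, the electron donor Por at -0.21 and the estrogen sulfotransferase Sult1e1 at -0.18, with unadjusted p-values of 0.129, 0.134 and 0.0522. Granulosa cell and follicle genes shifted upward, 16 of 19 higher (adjusted p = 0.00463, and adjusted p = 0.656 with an estimated correlation). Of the 19 genes, 1 had an unadjusted p under 0.05, and the groups did not overlap in 1. Their activin subunit Inhba was at +0.64 (SE 0.20, unadjusted p = 0.0162), Fgl2 at +0.26 (its 3 other probe sets at -0.048, 0.10 and 0.018) and Serpine2 at +0.25, and the call was lost without lean pool 1 (+0.19, adjusted p = 0.0745). Cell cycle genes shifted upward, 29 of 32 higher (adjusted p = 1.24e-07, and adjusted p = 0.638 with an estimated correlation), with any 1 pool left out as well. The mitotic checkpoint kinases Bub1b (+0.45, SE 0.10) and Bub1 (+0.30, SE 0.086) and cyclin Ccnb2 (+0.32, SE 0.079) were among 10 members higher at an unadjusted p under 0.05. The exception was the mitotic kinase Aurkb at -1.58 (SE 0.41), whose values were -2.17 in overfed pool 1 and -0.34 in overfed pool 2. Rsph1, a gene of the ciliary axoneme, had -2.02 and -0.27 in the same pools. Corpus luteum genes (17 of 22 lower, mean -0.08, adjusted p = 0.161), theca and interstitial genes (7 of 13 higher, mean +0.10, adjusted p = 0.441, with Insl3 at +0.10), oocyte genes (5 of 10 higher, mean +0.05, adjusted p = 0.596) and ovulation and prostaglandin genes (16 of 21 higher, mean +0.12, adjusted p = 0.274) did not pass. Without overfed pool 1 the ovulation mean was 0.021 and the theca mean 0.050, and without overfed pool 2 the ovulation mean was 0.19. The corpus luteum list did pass without lean pool 3 (-0.14, adjusted p = 0.0136), overfed pool 2 (-0.16, adjusted p = 0.0296) or overfed pool 3 (-0.14, adjusted p = 0.0451), and its mean was +0.054 without overfed pool 1 and 0.0041 without lean pool 2.

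Most lists of lipid genes had means below 0. Fatty acid synthesis shifted downward by a mean of -0.26, with 17 of 21 genes lower (adjusted p = 0.00276, and adjusted p = 0.638 with an estimated correlation). Its members with the lowest p-values were Pnpla3 (-0.996, SE 0.36, with -0.18 and -1.10 in its other probe sets), fatty acid synthase Fasn (-0.55, SE 0.20), the desaturase Scd (-0.74, SE 0.30) and the acyl-CoA ligase Acsl3 (-0.35, SE 0.15). The call was lost without lean pool 1 (-0.20, adjusted p = 0.094) and without overfed pool 1 (-0.20, adjusted p = 0.0622). With the oviduct list's mean as a covariate it was -0.066 (adjusted p = 0.478). Adipocyte markers had a mean of -0.21, with 12 of 15 lower (adjusted p = 0.0448, and adjusted p = 0.679 with an estimated correlation). They included Thrsp (-0.86), Cidec (-0.54), the glycerol channel Aqp7 (-0.41), Adipoq (-0.26) and Lep (-0.14), with Ucp1 at +0.17. None of those had an unadjusted p under 0.05, and the call was lost with quantile normalization (-0.21, adjusted p = 0.108), with array median centring (-0.22, adjusted p = 0.0584) and without lean pool 3 (-0.063, adjusted p = 0.493), lean pool 1 (-0.22, adjusted p = 0.0745), overfed pool 2 (-0.14, adjusted p = 0.172) or overfed pool 3 (-0.21, adjusted p = 0.0711), among other settings, while without lean pool 2 the mean was -0.34. Antioxidant genes had a mean of -0.12, with 25 of 29 lower (adjusted p = 0.0206, and adjusted p = 0.656 with an estimated correlation). The glutathione transferases Gstm1 (-0.54, SE 0.13), Gsta3 (-0.31) and Gstm2 (-0.25) and the peroxidase Gpx3 (-0.35) had the lowest p-values. Of the 29 genes, only Gstm1 had an unadjusted p under 0.05, and the groups did not overlap in 2. The call was lost without lean pool 1 (-0.12, adjusted p = 0.0545), lean pool 2 (-0.11, adjusted p = 0.167) or overfed pool 1 (-0.096, adjusted p = 0.211). It was also lost with the SD filter (-0.209, adjusted p = 0.0784) and without lean pool 3 and overfed pool 1 together (-0.0946, adjusted p = 0.0669). Cholesterol synthesis and uptake had 19 of 20 genes lower, with a mean of -0.12 (adjusted p = 0.216). The call and its direction hung on single pools. The list passed as lower without lean pool 3 (-0.27, adjusted p = 0.00444), overfed pool 2 (-0.31, adjusted p = 0.000852) or overfed pool 3 (-0.22, adjusted p = 0.0451), and as higher without overfed pool 1 (+0.18, adjusted p = 0.0246). Lipid uptake and storage (-0.09, adjusted p = 0.161), fatty acid oxidation (-0.08, adjusted p = 0.351), insulin and IGF signalling (-0.08, adjusted p = 0.146) and glycolysis (-0.14, adjusted p = 0.171) did not pass. Insulin and IGF signalling did pass without lean pool 2 (-0.13, adjusted p = 0.0175) and was at -0.016 without lean pool 3, and lipid uptake passed without overfed pool 3 (-0.12, adjusted p = 0.047) and was at -0.014 without lean pool 3. Without overfed pool 1 the mean of fatty acid oxidation was -0.013 and that of glycolysis -0.071.

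The oviduct and ciliated epithelium list had the largest shift of the 37 lists. Of its 20 genes 13 were measured, and Ovgp1 and Muc16 were among those not found. All 13 measured genes were lower in overfed ovaries (adjusted p = 7.46e-11, and adjusted p = 0.638 with an estimated correlation). Of these, 10 had an unadjusted p under 0.05 and 7 passed adjusted over the list alone, against 0 over all probe sets. Foxj1, the master regulator of motile cilia, was at -1.06 (SE 0.21, 2.09-fold lower). The microtubule proteins Tekt1 and Tekt2 were at -1.16 (SE 0.28) and -1.63 (SE 0.38), and the radial spoke protein Rsph1 at -1.69 (SE 0.41). The list's 5 ciliary genes had a median of -1.16, and its 8 other epithelial genes, such as keratins and Pax8, a median of -0.61. These 8 genes do not mark the oviduct alone. The list's means were 0.54, -0.02 and 0.78 in the lean pools and -0.49, -0.20 and -0.70 in the overfed pools. Its 5 ciliary genes alone had means of 0.53, 0.21 and 0.81 in the lean and -1.43, -0.21 and -0.80 in the overfed pools. In overfed pool 1 the other genes therefore lay well above the ciliary ones. The shift was -0.72 to -1.12 with any 1 pool left out, and past the adjusted threshold each time. Smooth muscle genes (mean -0.02, adjusted p = 0.925, with Acta2 at -0.37 and Actg2 at +0.19) spread widely inside both groups, from -0.76 to 0.54 over the lean and from -0.40 to 0.65 over the overfed pools, and passed without lean pool 2 (-0.41, adjusted p = 0.00448) but not without lean pool 3 (+0.24).

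Among genes whose groups did not overlap and whose unadjusted p was under 0.01, the 10 with the most negative differences, none past the adjusted threshold, were Lbp (-2.21, 4.63-fold lower), Iqca1 (-1.88), the transcription factor Myb (-1.82), Mlf1 (-1.76), Drc12 (-1.75), the dynein light chain Dynlrb2 (-1.73), the urea transporter Slc14a1 (-1.70), Rsph1 (-1.69), the epithelial integrin subunit Itgb6 (-1.68) and Cfap161 (-1.66). Their unadjusted p-values ran from 0.000294 for Lbp to 0.00738 for Mlf1, and their adjusted p-values from 0.623 to 0.626. The 10 most positive differences under the same limits were smaller. They were the extracellular matrix protein Coch (+1.22, SE 0.26, 2.33-fold higher), Slfn4 (+1.02), Cxcl10 (+0.97), Ccl2 (+0.80), Isg15 (+0.71), the transcription factor Foxp2 (+0.69), the guanylate-binding protein Gbp7 (+0.66), Ms4a6a (+0.65), the protocadherin Pcdh10 (+0.64) and the exonuclease Xrn1 (+0.60), with adjusted p-values of 0.623 to 0.644. Of the other 2 probe sets of Xrn1, 1 had the opposite sign. The other probe set of Slfn4 was at 0.043 (unadjusted p = 0.625) and that of Slc14a1 at -0.33.

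**Figure D3:**
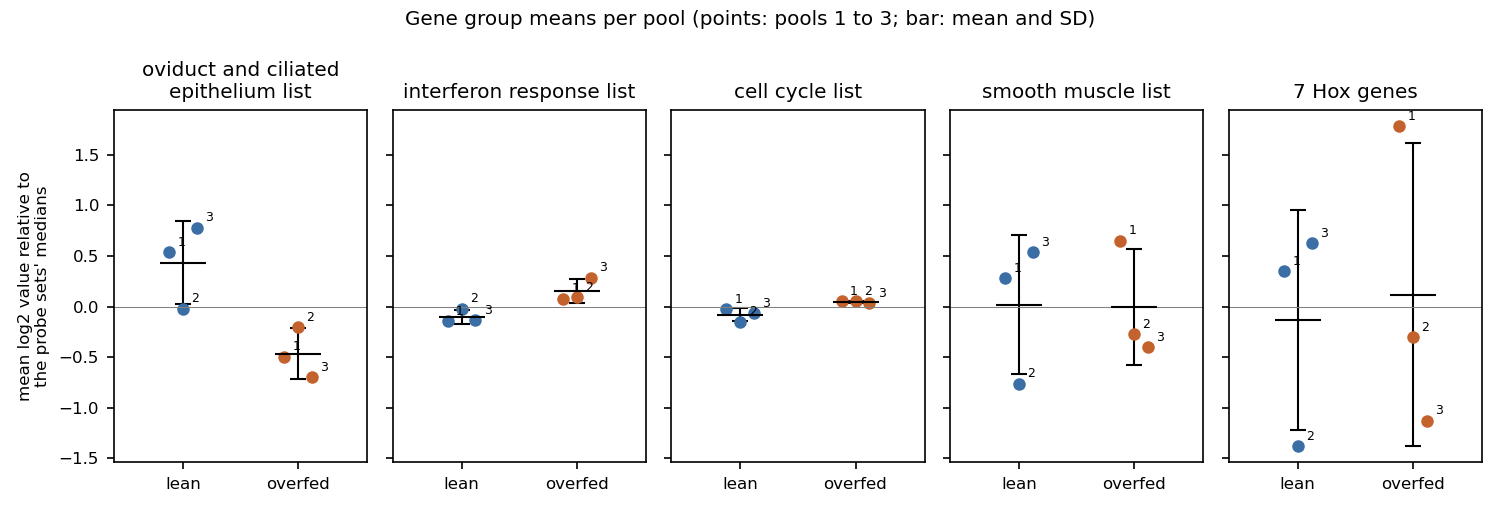
Mean log2 values, relative to the probe sets' medians, of 4 gene lists and of 7 Hox genes in each pool, with the pools as numbered points and the group mean and SD as bars. The oviduct list separates lean from overfed pools, whereas the smooth muscle list and the Hox genes differ more between pools of one group than between the groups.

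The other lists did not pass camera's threshold either. Their means were +0.08 for extracellular matrix (adjusted p = 0.274), +0.08 for matrix proteases (adjusted p = 0.48), +0.05 for angiogenesis and hypoxia (adjusted p = 0.441), +0.05 for endothelial markers (adjusted p = 0.441, with Pecam1 at -0.12 and Kdr at -0.15, or 0.018 in its other probe set), +0.03 for the unfolded protein and heat shock response (adjusted p = 0.42) and +0.04 for ribosomal proteins (adjusted p = 0.205). Extracellular matrix passed without lean pool 3 (+0.21, adjusted p = 0.00641) or overfed pool 2 (+0.20, adjusted p = 0.00565) and was at -0.061 without lean pool 2 and -0.060 without overfed pool 1. Ribosomal proteins passed without lean pool 3 (+0.068, adjusted p = 0.0386) or overfed pool 3 (+0.066, adjusted p = 0.0451) and were at 0.0064 without overfed pool 1. Without that pool the protease mean was 0.0066 and that of the unfolded protein response 0.0095, and the angiogenesis mean was 0.019 without overfed pool 3. The endothelial median was -0.0030. The circadian clock (-0.02, adjusted p = 0.494) and the mitochondrial respiratory chain (-0.02, adjusted p = 0.494) lay near 0. So did the reference genes, whose mean of 0.0078 (adjusted p = 0.816) turned to -0.00029 with array median centring. Red blood cell genes had a mean of 0.0048, a median of -0.041 and a camera direction downward (adjusted p = 0.633), with Hba-a3 at +0.55 and Hbb at -0.19, and their mean turned to -0.0032 with array median centring.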

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

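The alternatives chosen after seeing the data were the trend alone, the SD filter, named probe sets only, both covariates, the joint omission of lean pool 3 and overfed pool 1, and the natural-log reading. Not run were the planned pseudocounts, which need linear values, and the planned filters on dim probe sets, which need levels. Under the SD filter, genes left out by it and lists with under 5 genes had no value. Signal over background, which limits dim probe sets, is not known from centred values. Of 2285 values recomputed under an alternative, 2094 kept their direction and side of the threshold (or a count within 1.5 times). Where no reason is given below, the cause was not tested. Probe sets past the adjusted threshold were 0 in every setting except the trend with a robust prior (1) and the larger-SD filter (62, with 15521 probe sets tested and a prior of 12.0 degrees of freedom against 3.07, so that unadjusted p-values changed as well). The count at an unadjusted p under 0.05 and 1.5-fold was 295 (without lean pool 3) to 650 (without lean pool 2) with 1 pool left out, with 44 to 90 higher and 251 to 576 lower. Higher probe sets numbered 78 with quantile normalization, 28 with named probe sets only, 167 with the oviduct covariate (178 lower) and 93 without lean pool 3 and overfed pool 1 (228 lower). Read as natural logarithms, the values gave 759, with 189 higher and 570 lower, because the fold threshold then lies lower. With the replicate block of pool numbers the count was 394, of which 376 were shared with the 403, and the same 9 lists passed. Same-numbered pools had correlations of deviations of 0.097, 0.17 and -0.284, not every pool correlated best with its own number, and the numbers were not taken to pair pools. Lists past camera's threshold numbered 4 to 12 with 1 pool left out, 0 with an estimated correlation and 0 in fry. The oviduct shift of -0.90 had adjusted p = 0.638 and 0.331 in those tests, as did the interferon shift of 0.25. Over all alternatives the adjusted p ran from 1.52e-15 to 0.638 for the oviduct list and from 2.64e-07 to 0.638 for the interferon list. With any 1 pool left out, the oviduct, interferon and cell cycle lists stayed past the threshold. With the SD filter the cytokine list passed (0.10, adjusted p = 0.0453, with adjusted p-values of 0.0453 to 0.73 over its alternatives), and the immediate-early and clock means turned to 0.0056 and 0.00024. Without lean pool 3 and overfed pool 1 the immediate-early list passed at -0.092 (adjusted p = 0.0461, 0.0461 to 0.989 over its alternatives), Egr1 was -0.055, cholesterol synthesis 0.029, complement 0.017, red blood cell genes -0.024, Actg2 -0.16 and Insl3 -0.0084. This omission ended the camera calls of B and plasma cells (-0.132, adjusted p = 0.268), antioxidant genes (-0.0946, adjusted p = 0.0669) and adipocyte markers (-0.125, adjusted p = 0.293). Egr4 was 0.0056 and Actg2 -0.17 with quantile normalization, and they were 0.029 and -0.044 with array weights. Actg2 was -0.046 with the Hox covariate. The red blood cell mean was -0.0032 with array median centring, -0.021 with array weights and -0.0086 with all probe sets averaged, and the reference mean was -0.00029 with centring. The oviduct covariate differs between the groups itself, so its fit leaves little of the group difference to estimate. It took the interferon mean to 0.066 (adjusted p = 0.495) and turned steroidogenesis to -0.088, insulin signalling to 0.094, complement to 0.29, oocyte to -0.095, angiogenesis to -0.073, T and NK cells to -0.081, mast cells to -0.025, endothelium to -0.11, smooth muscle to 1.06, adipocytes to 0.14, red blood cells to -0.0096 and reference genes to -0.083. Under it corpus luteum (-0.28, adjusted p = 0.00916), extracellular matrix (0.40, adjusted p = 0.00348), MHC class II (-0.31, adjusted p = 0.00348), respiratory chain (-0.097, adjusted p = 0.0448), ribosomal genes (0.11, adjusted p = 0.0296), smooth muscle (adjusted p = 8.3e-08) and endothelium (adjusted p = 0.0424) passed. Under it the single genes that turned were Egr4 (0.27), Cyp17a1 (-0.13), Hsd17b1 (-0.26), Pnpla3 (0.30), Scd (0.13), Gsta3 (0.043), Mx1 (-0.040), Inhba (-0.038), Pou2af1 (0.0076), Thrsp (0.30), Cd68 (-0.29), Adgre1 (-0.093), Cma1 (-0.28), Acta2 (1.25), Adipoq (0.69) and Insl3 (-0.46). With 1 pool left out, these means changed sign: immediate-early genes (-0.073 to 0.059), cholesterol (-0.31 to 0.18), respiratory chain (-0.051 to 0.0068), clock (-0.045 to 0.0060), complement (-0.12 to 0.080), oocyte (-0.038 to 0.11), corpus luteum (-0.16 to 0.054), extracellular matrix (-0.061 to 0.21), T and NK cells (-0.0073 to 0.12), mast cells (-0.0081 to 0.064), endothelium (-0.017 to 0.094), smooth muscle (-0.41 to 0.24), red blood cells (-0.029 to 0.058) and reference genes (-0.013 to 0.039). The single genes that did so were Egr4 (-0.13 to 0.12), Cd68 (-0.082 to 0.13), Cd3e (-0.15 to 0.30), Cma1 (-0.19 to 0.21), Acta2 (-0.95 to 0.23), Actg2 (-0.55 to 0.60), Adipoq (-0.60 to 0.038), Hbb (-0.34 to 0.053) and Insl3 (-0.069 to 0.28). With 1 pool left out, single genes that moved by over 1.5 times without a change of sign were Egr1 (0.048 to 0.42), Jchain (-0.72 to -0.16), S100a8 (0.62 to 1.46), Cd79b (0.052 to 0.19), Egr3 (-0.25 to -0.10), Dusp1 (-0.47 to -0.18), Hsd17b1 (0.21 to 0.56), Por (-0.30 to -0.11), Pnpla3 (-1.38 to -0.65), Fasn (-0.70 to -0.32), Acsl3 (-0.43 to -0.20), Gsta3 (-0.44 to -0.19), Gpx3 (-0.49 to -0.13), Gstm2 (-0.42 to -0.079), Fgl2 (0.17 to 0.37), Serpine2 (0.16 to 0.37), Thrsp (-1.21 to -0.57), Aqp7 (-0.58 to -0.23), Cidec (-0.76 to -0.29), Adgre1 (0.12 to 0.31), Cd74 (-0.31 to -0.13), RT1-Da (-0.23 to -0.037), Cd3d (0.095 to 0.25), Cpa3 (0.14 to 0.35), Pecam1 (-0.22 to -0.058), Kdr (-0.24 to -0.00022) and Lep (-0.21 to -0.049). Over all alternatives further moves of this size were seen, such as Fasn to -0.0045, Slfn4 to 0.19 and Foxj1 to -0.33.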

Other observations

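The tests in this part were chosen after the results were seen, except the counts over other splits of the pools. Genes whose symbols mark parts of the motile cilium were lower as families. Of 19 Cfap genes, which encode cilia and flagella associated proteins, 18 were lower, with a median of -0.82, and 10 were among the 246 genes, of 14217, that were lower at an unadjusted p under 0.05 and 1.5-fold. The axonemal dynein heavy chains (Dnah) contributed 3 of 4, the radial spoke genes (Rsph) 3 of 5 and the tektins (Tekt) 3 of 6, and all 4 family medians stayed below 0 with quantile normalization and with array median centring. These are counts without a test, since the families were picked after ciliary genes had been seen among the largest differences, include members of the oviduct list and move together between pools.

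A different set of genes separated pools of the same diet. Hoxa10, a homeobox gene of the uterus, had values of 0.46, -3.18 and 1.23 in the lean pools and 3.04, -0.46 and -2.57 in the overfed pools, the widest range of all probe sets at 6.22. Hoxd10 ran from -2.52 in lean pool 2 to 3.12 in overfed pool 1, and Hoxa11 from -1.33 to 3.04 in the same pools. Hoxa9 lay between -2.06 and 1.66. The steroid enzyme Hsd11b2 reached 2.11 in overfed pool 1 and -0.73 in lean pool 2, and the progesterone receptor gene Pgr 1.26 and -1.14. Of the other 16 genes of a uterus list written before they were looked up, Muc4 (range 1.85), Muc1 (1.69), Foxa2 (1.55), Hoxd9 (1.53), Hoxb7 (1.10), Emx2 (1.05) and Esr1 (1.02) spread more widely than the remaining 9, which had ranges of 0.25 to 0.80. In Muc1 and Muc4 all 3 overfed pools lay below all 3 lean pools, with Muc1 at 0.48, 0.13 and 0.93 in the lean and -0.13, -0.47 and -0.76 in the overfed pools. In Wnt4 they lay above, at -0.33, -0.12 and -0.028 in the lean and 0.39, 0.028 and 0.093 in the overfed pools. How many of the genes of the uterus and oviduct lists the ovary itself expresses is not known from centred values.

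The lower level of oviduct genes in the overfed pools was weighed first. Of 346 lower probe sets outside the list, 59% followed the list's 5 ciliary genes inside the groups (within-group r over 0.8), against 4.64% of all probe sets and 2 of the 48 higher ones. The 8 epithelial genes without a ciliary role had a median of -0.61. In overfed pool 1, however, the ciliary genes had a mean of -1.43 and the whole list one of -0.49. Both parts of the list thus did not move alike in that pool, and the median does not show a shared tissue amount. The lower probe sets include further ciliary genes, such as those of the Cfap family, so the share that followed cannot tell tissue amount from an effect on cilia. Different amounts of oviduct tissue left on the dissected ovaries are a candidate explanation. The RNA quality of lean pool 3 was argued against as the whole cause, since the list's mean without that pool was -0.721. An effect of overfeeding on cilia of the oviduct or of the ovarian surface was not tested and stays open, as the design gives no measure of tissue amounts.

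The spread of Hox genes between pools of 1 group was weighed next. In the smooth muscle list, 15 of 16 genes had their lowest value in lean pool 2 and 10 of 16 their highest in overfed pool 1, where chance gives 16.7% for a pool. These genes are not independent draws (estimated correlation 0.81), and the pools were picked after the Hox values were seen. The counts therefore describe a shared movement and are no test against that share. Different amounts of uterine or adjoining duct tissue in the pools may account for this, as smooth muscle and Hox genes move together. Array quality of overfed pool 1 was argued against as the whole cause, since that pool was highest or lowest in 0 of 4 control measures and Hoxa10 ran from -3.18 to 1.23 between lean pools alone, but the pool had the largest SD (0.29) and the second-lowest array weight (0.65). No biological explanation was tested.

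The higher interferon list was the third pattern. A smaller share of oviduct RNA would raise all ovarian genes alike, and granulosa (+0.22, SE 0.061) and theca genes (+0.10, SE 0.088) went that way. The corpus luteum list was at -0.082 (SE 0.048 over genes) and, without overfed pool 1, at +0.054 against an interferon mean of +0.29. Its pool means were -0.067, 0.16 and -0.13 in the lean and -0.37, 0.062 and 0.024 in the overfed pools (exact permutation test p = 0.7). That spread between pools is too wide for the list to decide on an equal dilution. A higher share of all immune cells would raise each immune list, but the lowest of 4, that of B and plasma cells, was -0.199 (SE 0.073). Without lean pool 3 the interferon mean was 0.236, so that array alone was not the source. A response of the ovary to overfeeding may explain the shift but was not tested apart from these, and the shift dropped to 0.066 with the oviduct list's mean as a covariate. As that covariate separates the groups itself, the drop cannot tell the oviduct list's level from diet.

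With 3 against 3 pools there are 10 splits, so a share under 0.05 cannot be reached. Probe sets past the adjusted threshold were 0 in the real split and at most 0 in the other splits, with 10 of 10 splits as large. At an unadjusted p under 0.05 and 1.5-fold the real split gave 403 probe sets and the highest other 747, and 2 of 10 splits gave as many as the real one. That highest split set lean pools 1 and 3 and overfed pool 1 against the rest, which is the order of the Hox and smooth muscle genes and points to a structure of the samples. With the Hox genes' mean as a covariate the real count was 494, of which 390 were shared with the 403. Lists past camera's threshold numbered 9 in the real split and 13 in the highest other, with 5 of 10 splits as large. The oviduct list's mean difference had a size of 0.896 in the real split and at most 0.776 in the others, but the list also passed camera in 4 of the 9 others (adjusted p = 1.14e-09, 3.98e-06, 0.00835 and 0.0483, against 7.46e-11), so that camera's p-value alone does not set the diet apart from other groupings.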
